A study of Mus musculus with 16 samples.

How the data were processed

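Interscapular brown fat of C57BL/6J mice was profiled by bulk RNA sequencing. Wild-type littermates (WT) and mice with a brown-fat-specific knockout of Akt2 (KO, made with a tamoxifen-inducible Cre recombinase under the Ucp1 promoter, named UCP1-CreER in the labels) were kept at 30 °C, a thermoneutral temperature for mice, or at 22 °C, for 4 weeks from 9 to 13 weeks of age. There were 4 libraries in each of the 4 groups and 16 libraries in all, grouped by their titles. The labels number the libraries as separate samples and do not say in so many words that each came from another animal, so p-values measure the spread between these samples.

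The deposited table holds raw read counts per Ensembl gene, 1 column per library, which were not normalised by the authors as far as the values show. Per the submitters' processing notes, FastQC 0.10.1, STAR 2.4.2a and edgeR 3.14.0 were used by the submitters and the genome builds were GRCm38 and mm10, with no role given for each. The counting program, annotation release and strand setting are not given in the sources used here. Per the labels' protocols, total RNA was isolated with a phenol-based reagent and columns, treated to remove DNA and made into libraries by standard Illumina procedures. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart, and genes with near-identical copies, such as Gapdh, Akt2-ps and mitochondrially encoded genes with nuclear copies, are uncertain.

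Gene symbols came from a reference table that matched 37607 identifiers and left 1317 without a symbol, which held at most 0.132% of the counts of a library. Coordinates are from GENCODE M21 on GRCm38. Library totals ranged from 12751528 to 23866743 counts. Of the 24818 genes with at least 1 count, 14103 passed edgeR's filterByExpr (minimum count 10) and were tested. They held at least 99.9% of the counts in every library.

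Counts were analysed in R 4.3.3 with edgeR 4.0.16. All 16 libraries entered 1 quasi-likelihood model with a term per group and trimmed-mean (TMM) factors. The 5 comparisons were KO against WT at each temperature, 22 °C against 30 °C in each genotype, and the difference between the KO effects at the 2 temperatures (the interaction). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Standard errors are the absolute log2 fold change divided by the square root of the quasi-likelihood F. Expression levels are counts scaled to TMM-adjusted library size (CPM), given as mean ± SD of 4 libraries. With a typical biological coefficient of variation of 22.5%, counting error was small for genes of moderate expression. Counts were simulated for KO against WT at 22 °C with 200 of 14103 genes changed. In them edgeR recovered 33 of 100 genes changed 1.5-fold and 63 of 100 changed 2-fold, with 3 wrong calls. For the interaction it recovered 4 of 100 and 26 of 100. In the real counts 2482 genes were called at 22 °C. The adjusted threshold is looser where more genes change, so these rates do not give the power there.

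The gene lists, 33 in number, were fixed before the data were examined, as were the design, the tests, the rule for naming genes and the first group of alternative settings below. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data, each adjusted over all 165 tests. A list member was counted as having risen or fallen by the adjusted p over all genes tested, and separately adjusted over the list alone. Genes were named by this rule: in each comparison Akt2, Akt1, Mlxipl, Srebf1 and Ucp1, then up to 4 members with the smallest p of each list that passed camera or had at least 2 changed members, then the 6 largest changes in each direction among called genes with a mean logCPM of at least 2, no overlap between the libraries of the groups compared (not required for the interaction), and no predicted-gene or pseudogene name. From a list that met neither condition, at most 2 members with the highest mean count could be named. Genes named outside it are marked, and 1 gene under the rule is not reported here.

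Alternative settings were relative-log-expression and upper-quartile factors, no filter, a stricter filter (CPM of at least 1 in 4 libraries and a mean count of 20), DESeq2 1.42.0, limma-voom with quality weights, fits on only the groups compared, the replicate number as a block, each library left out in turn, the estimated inter-gene correlation, and splitting the WT libraries at 22 °C between comparisons that share them. Alternatives chosen after seeing the data were a skeletal muscle covariate, leaving out the 5 libraries with over 0.1% of counts on skeletal muscle markers, a circadian clock covariate (log2 CPM of Dbp minus that of Arntl), and factors computed without the 50 most abundant genes and the lipogenesis list. Those 5 libraries are called muscle-bearing below, although the others also held such counts, at up to 0.0836%. Libraries within a group differed by more than sampling noise in all 24 pairs (lowest chi-square per gene 7.68), so none was treated as a duplicate.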

Results

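The data were 16 bulk RNA-seq libraries of mouse interscapular brown fat, a heat-producing fat depot, with 4 libraries each from WT and KO mice at 30 °C and at 22 °C. Total counts per library ranged from 15303069 to 16022550 in WT at 30 °C, from 12751528 to 17020621 in KO at 30 °C, from 14563657 to 23866743 in WT at 22 °C and from 15117483 to 16871456 in KO at 22 °C. The design asks how brown fat adapts to ambient temperature and how that depends on AKT2, a kinase that acts downstream of the insulin receptor.

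The targeted gene, Akt2 (ENSMUSG00000004056, chromosome 7, 27591552 to 27640826, plus strand, GRCm38), was lower in every KO library than in every WT library. At 30 °C its level was 204 ± 12.9 CPM in WT and 69.4 ± 10.7 CPM in KO (SD, n = 4). At 22 °C it was 232 ± 19.8 CPM in WT and 82.2 ± 6.03 CPM in KO. The log2 fold change was -1.55 (SE 0.105, adjusted p = 2.13e-06) at 30 °C and -1.50 (SE 0.105, adjusted p = 5.06e-07) at 22 °C, and the difference between them did not pass the test (adjusted p = 0.847). The remaining Akt2 signal was measured in whole tissue.

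The first comparison asked what a lower ambient temperature does to WT brown fat. Genes of de novo fatty acid synthesis rose, with the largest median increase of the 33 lists. Fasn, which encodes fatty acid synthase, went from 1736 ± 1167 CPM at 30 °C to 31088 ± 3356 CPM at 22 °C (n = 4 each), and the share of all counts on the lipogenesis list went from between 1.08% and 2.49% per library at 30 °C to 8.33% ± 1.54 at 22 °C. Of the 16 lipogenesis genes, 13 rose and 2 fell, with the same numbers adjusted over the list alone and a median log2 fold change of 2.32. The members Slc25a1, the mitochondrial citrate carrier, and Elovl6, a fatty acid elongase, rose by 2.97 (SE 0.133) and 3.40 (SE 0.187). The desaturase genes Fads1 and Fads2, named outside the rule as the members that fell, had log2 fold changes of -0.82 and -0.70. The list passed camera (adjusted p = 8.74e-27, and adjusted p = 0.0042 with an estimated correlation).

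Cholesterol synthesis and pentose phosphate genes rose with it in WT. In the cholesterol list 19 of 25 genes rose and none fell (19 rose and 1 fell adjusted over the list alone, adjusted p = 0.0271 with an estimated correlation), including Nsdhl (log2 fold change 2.19) and Pmvk (2.46). In the pentose phosphate list, whose enzymes supply NADPH, 6 of 7 rose (6 adjusted over the list alone, adjusted p = 0.0250 with an estimated correlation), including Pgd (2.69) and Tkt (1.93). In glucose uptake and glycolysis 14 of 19 genes rose and 1 fell (15 and 1 adjusted over the list alone), among them Ldha (1.62). The camera call was lost at adjusted p = 0.128 with an estimated correlation. Gapdh, whose reads can be shared with many processed copies, had a log2 fold change of 1.57.

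Nuclear-encoded mitochondrial genes and thermogenic genes also rose in WT at 22 °C. All 19 genes of the TCA cycle and pyruvate dehydrogenase rose (19 adjusted over the list alone, adjusted p = 0.0743 with an estimated correlation), for example Pdhx by 1.46 and Pdhb by 1.84. Of 55 nuclear-encoded oxidative phosphorylation genes 53 rose (53 adjusted over the list alone, adjusted p = 0.288 with an estimated correlation), for example Sdha by 0.81 and Sdhd by 0.93. Mitochondrially encoded genes, uncertain because of nuclear copies, did not rise with them. None of 8 rose and 3 fell (3 adjusted over the list alone, median -0.15), and the list did not pass camera (adjusted p = 0.0717). Their share of raw counts, without TMM factors, went from 24.1% ± 1.30 to 16.9% ± 3.15. At 22 °C it was 12.3% in WT replicate 2 and 18.1% to 18.8% in the other WT libraries. Without WT replicate 2 or 4 at 30 °C or WT replicate 2, 3 or 4 at 22 °C 2 of the 8 genes fell. In fatty acid oxidation 17 of 22 rose and 1 fell (18 and 1 adjusted over the list alone, adjusted p = 0.186 with an estimated correlation), with Acot11 at 3.04 and Cpt2 at 1.39. In the thermogenic and brown adipocyte list 12 of 23 rose and 3 fell (12 and 3 adjusted over the list alone, adjusted p = 0.198 with an estimated correlation). With any 1 library left out 2 were lower, or 1 without WT replicate 1, 3 or 4 at 30 °C or WT replicate 3 or 4 at 22 °C. The lower gene in fatty acid oxidation was lost without any library except WT replicate 4 at 22 °C. Ucp1, the uncoupling protein of brown fat mitochondria (ENSMUSG00000031710 in the annotation), went from 1518 ± 92.2 to 6178 ± 2462 CPM (log2 fold change 2.03, SE 0.253), the elongase gene Elovl3 rose by 6.17 (SE 0.625) and Letmd1 by 1.29.

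Other metabolic lists passed camera at the preset correlation but not with an estimated one in WT. In triglyceride synthesis and glycerol metabolism 8 of 14 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.59, adjusted p = 7.11e-05, and 0.224 with an estimated correlation). In glycogen metabolism 8 of 13 rose and 1 fell (8 and 2 adjusted over the list alone, 0.0901 with an estimated correlation), and 2 fell without WT replicate 1 at 30 °C or WT replicate 4 at 22 °C. In branched-chain amino acid catabolism 14 of 17 rose (14 adjusted over the list alone, 0.238 with an estimated correlation). In fatty acid uptake 6 of 13 rose and 3 fell (6 and 3 adjusted over the list alone, adjusted p = 0.0334, and 0.547 with an estimated correlation). In lipolysis 7 of 13 rose and 1 fell (7 and 1 adjusted over the list alone, 0.0264 and 0.439). The last 2 calls were lost without WT replicate 2 at 30 °C (0.0518 and 0.0519) or WT replicate 2 at 22 °C (0.0964 and 0.0679). Fatty acid uptake was also lost with the stricter filter (0.0520), limma-voom (0.215) and the clock covariate (0.0709), and lipolysis without muscle-bearing libraries (0.0559).

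Cell cycle, interferon, macrophage and endothelial transcripts were lower in WT at 22 °C. In the proliferation list 17 of 23 genes fell (21 adjusted over the list alone, adjusted p = 0.288 with an estimated correlation), among them Kif11 (-2.05) and Top2a (-1.95). In the interferon list 12 of 16 fell (14 adjusted over the list alone, adjusted p = 0.478 with an estimated correlation), including Mx1 (-2.37) and Usp18 (-1.28). Of 14 macrophage markers 10 fell (11 adjusted over the list alone, adjusted p = 0.498 with an estimated correlation), including Trem2 (-1.86) and Ctss (-1.53). Of 12 endothelial markers 8 fell (9 adjusted over the list alone, adjusted p = 0.0628 with an estimated correlation), including Tie1 (-0.76) and Cdh5 (-0.76). Of 11 lymphocyte markers 1 fell (0 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.307). It had none lower without WT replicate 1 or 2 at 30 °C or WT replicate 1 or 4 at 22 °C, and 2 without WT replicate 3 at 22 °C. Of 17 extracellular matrix genes 7 fell (7 adjusted over the list alone, adjusted p = 0.566 with an estimated correlation), and 4 without WT replicate 1 at 30 °C.

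Within the level and overlap limits of the naming rule, the largest changes in WT were those of Mfsd2a (log2 fold change 6.38), Elovl3, Adprhl1 (5.52), the fructose transporter gene Slc2a5 (4.95), Fasn (4.16) and Aspg (4.14) among those that rose, and Igha (-4.49), Mmp12 (-4.26), Nnat (-4.17), Fras1 (-3.93), Rab17 (-3.49) and Cpne9 (-3.28) among those that fell. Mfsd2a was 41.9 ± 56.8 CPM in WT at 22 °C, an SD above the mean. Adprhl1 had a mean of 0.35 CPM at 30 °C. Igha, Mmp12, Fras1, Rab17 and Cpne9 had means of 0.59 to 0.97 CPM at 22 °C. The sizes of these changes are therefore uncertain. Mlxipl and Srebf1, which encode the lipogenic transcription factors ChREBP and SREBP1, rose by 0.85 (SE 0.126) and 0.59 (SE 0.200). The Srebf1 call was lost with upper-quartile factors (0.50, adjusted p = 0.0602), without muscle-bearing libraries (0.45, 0.113) and with the clock covariate (0.53, 0.0786), and, at 0.48 to 0.58, without WT replicate 2 or 4 at 30 °C (adjusted p = 0.0815 and 0.0609) and without WT replicate 2, 3 or 4 at 22 °C (adjusted p = 0.0534, 0.0866 and 0.0501). Akt1 (-0.19, adjusted p = 0.0797) and Akt2 (0.19, adjusted p = 0.164) did not pass. In total 5406 of 14103 genes changed, 2897 higher and 2509 lower at 22 °C. With upper-quartile factors, which moved the median log2 fold change of all genes to -0.13, 2196 were higher and 3382 lower. Without the 5 muscle-bearing libraries 3386 genes were called.

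**Figure D1:**
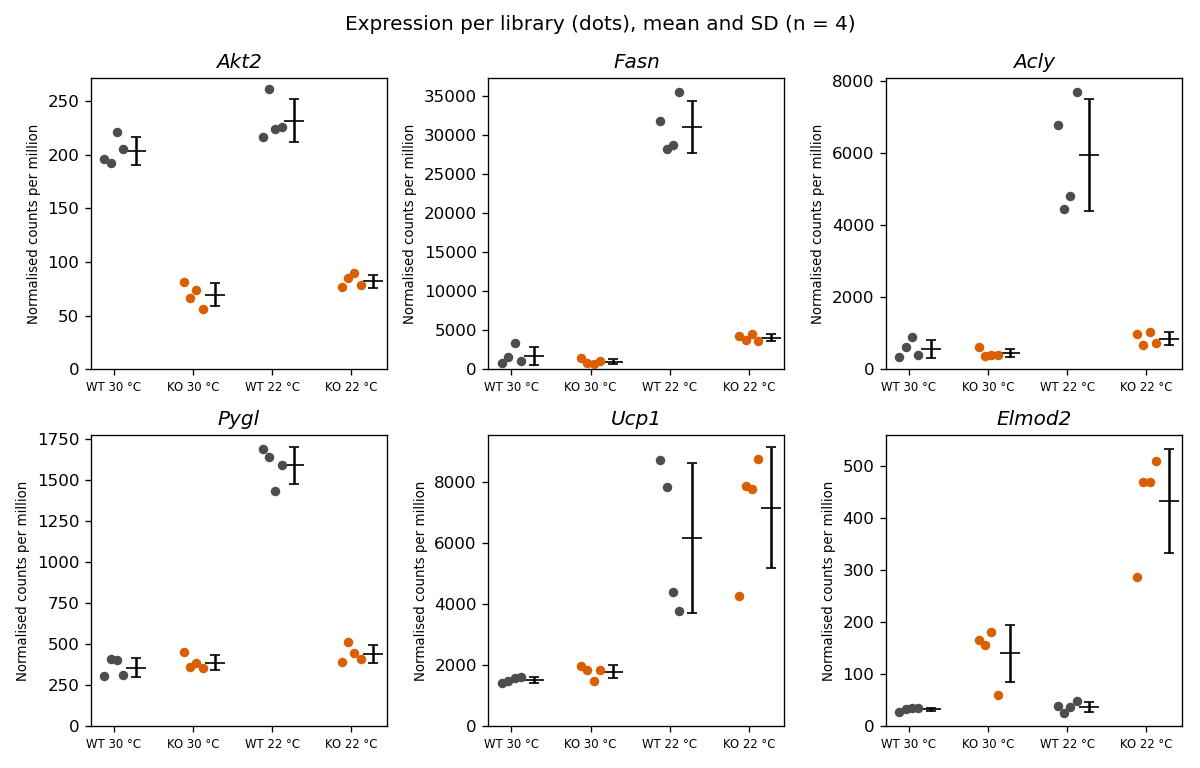
Normalised counts in CPM (vertical axis, from 0) of 6 genes in each library (dots) by group, with the mean and SD of 4 libraries as bars. Fasn, Acly and Pygl are high only in the WT group at 22 °C among these 4 groups, with Fasn at 31088 CPM there and 4050 CPM in KO at 22 °C, while the Ucp1 means at 22 °C are 6178 CPM in WT and 7165 CPM in KO.

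In KO brown fat the same change of temperature raised thermogenic genes and lowered proliferation genes. Ucp1 rose by 2.00 (SE 0.253), Dio2, which encodes the enzyme that activates thyroid hormone, by 4.43 and Ppargc1a, a coactivator of mitochondrial gene expression, by 2.41. In the thermogenic list 9 of 23 genes rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 0.138 with an estimated correlation), with none lower without KO replicate 1 or 4 at 30 °C or KO replicate 2, 3 or 4 at 22 °C. In the proliferation list 21 of 23 fell (21 adjusted over the list alone, adjusted p = 0.102 with an estimated correlation), with Top2a at -2.32 and Kif11 at -1.59. Of 14 macrophage markers 10 fell (11 adjusted over the list alone, adjusted p = 0.288 with an estimated correlation), with Trem2 at -2.36 and Ctss at -1.68. In triglyceride synthesis and glycerol metabolism 8 of 14 rose and 1 fell (10 and 2 adjusted over the list alone, adjusted p = 0.140 with an estimated correlation), including glycerol kinase Gk (3.43) and Dgat1 (1.06), and none fell without KO replicate 3 at 30 °C or KO replicate 1 or 4 at 22 °C. Of the oxidative phosphorylation genes 22 of 55 rose (24 adjusted over the list alone, adjusted p = 0.690 with an estimated correlation), of the TCA list 11 of 19 (12 adjusted over the list alone, adjusted p = 0.478 with an estimated correlation) and of fatty acid oxidation 13 of 22 (14 adjusted over the list alone, adjusted p = 0.414 with an estimated correlation). These counts moved with single libraries, and with any 1 left out oxidative phosphorylation had 11 to 19. Without KO replicate 2 or 4 at 22 °C they were 11 and 11 for oxidative phosphorylation, 8 and 7 for the TCA list and 8 and 8 for fatty acid oxidation, and without KO replicate 2 or 4 at 30 °C oxidative phosphorylation had 14 and 13. Of the 8 mitochondrially encoded genes 2 fell and none rose (3 fell adjusted over the list alone, camera adjusted p = 0.0532).

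In KO 7 other lists passed camera at the preset correlation but not with an estimated one. In what follows the number adjusted over the list alone and the adjusted p with an estimated correlation come last. Those that rose were pentose phosphate (4 of 7 rose, 4, 0.414), lipolysis (5 of 13 rose, 5, 0.415), fatty acid uptake (6 of 13 rose and 2 fell, 6 and 3, 0.555) and branched-chain amino acid catabolism (11 of 17 rose and 1 fell, 11 and 1, 0.415). Those that fell were interferon (5 of 16 fell, 5, 0.587), extracellular matrix (5 of 17 fell, 5, 0.663) and endothelial markers (5 of 12 fell, 5, 0.138). Fatty acid uptake (adjusted p = 0.0344) lost its call without KO replicate 2 at 30 °C (0.0550) or KO replicate 3 at 22 °C (0.0747), with the stricter filter (0.0508), with only the groups compared (0.129) and with the replicate block (0.0550). Lipolysis lost it with limma-voom (0.112) and interferon with the clock covariate (0.308). The branched-chain count became 7 without KO replicate 2 or 4 at 22 °C. The interferon count became 8 without KO replicate 4 at 30 °C or KO replicate 1 at 22 °C, and the matrix count 2 without KO replicate 2 at 30 °C and 3 without KO replicate 2 at 22 °C. In lipolysis 1 fell without KO replicate 3 at 30 °C or KO replicate 1 at 22 °C, and without the latter 1 matrix gene rose.

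Lipogenic genes had a median log2 fold change of 0.87 in KO. Of the 16 genes 11 rose and 1 fell (11 and 3 adjusted over the list alone, adjusted p = 0.118 with an estimated correlation), with Elovl6 at 2.28 and Slc25a1 at 1.14, and 2 fell without KO replicate 1 at 22 °C. Fasn reached 4050 ± 437 CPM at 22 °C, from 988 ± 363 CPM at 30 °C. Within the same limits the largest changes were those of Mfsd2a (6.57), Dio2, Elovl3 (4.06), Nr4a3 (3.58), Gk and Fndc5 (3.37) among genes that rose, and Mmp12 (-6.34), Rab17 (-3.95), Rgs11 (-3.52), Nnat (-3.09), Tusc3 (-2.78) and Spag5 (-2.77) among those that fell. Means were low for Mfsd2a in KO at 30 °C (0.86 CPM) and for Mmp12, Rab17, Rgs11 and Spag5 in KO at 22 °C (0.22 to 1.00 CPM). The sizes of these changes are therefore uncertain. Mlxipl (0.29), Srebf1 (-0.27), Akt1 (0.02) and Akt2 (0.24) did not pass. In total 3772 genes changed, 1943 higher and 1829 lower. With upper-quartile factors 1179 were higher and 2540 lower. Without the muscle-bearing libraries 1755 genes were called, and limma-voom called 6067. Of the genes higher at 22 °C, 1286 were called in both genotypes, against 399 for independent lists of those sizes, and of the lower genes 1119 were, against 325.

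**Figure D2:**
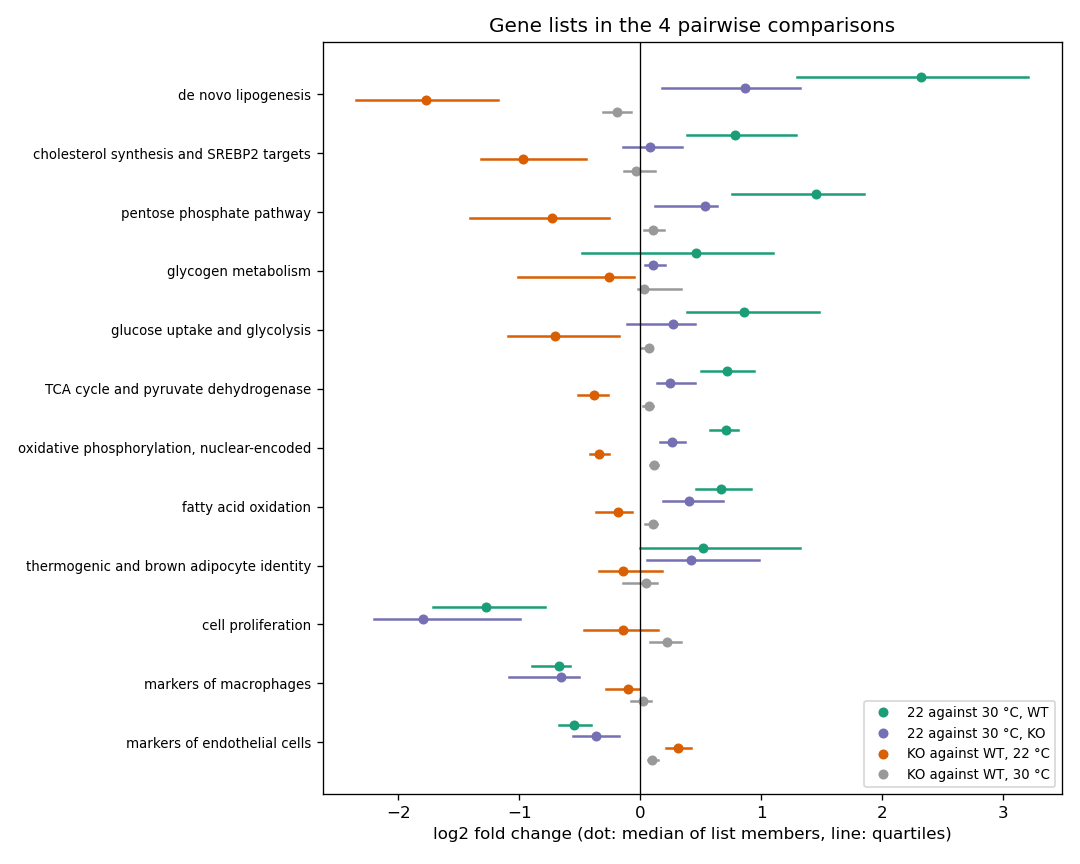
Log2 fold change (horizontal axis) of 12 gene lists in the 4 pairwise comparisons, with the median of the list members as a dot and the quartiles as a line. The median of the lipogenesis list is 2.32 for 22 °C against 30 °C in WT, 0.87 in KO, -1.77 for KO against WT at 22 °C and -0.19 for KO against WT at 30 °C.

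The next comparison asked what the loss of AKT2 changes at 22 °C. Lipogenic genes fell. Fasn was 31088 ± 3356 CPM in WT and 4050 ± 437 CPM in KO (log2 fold change -2.94, SE 0.364, adjusted p = 9.64e-05, and -2.94 at adjusted p = 0.0701 with the clock covariate), and the lipogenesis list took 8.33% ± 1.54 of counts in WT and 1.81% ± 0.339 in KO. In this list 13 of 16 genes fell and none rose (14 fell adjusted over the list alone), with a median of -1.77, and the list passed camera (adjusted p = 1.58e-33, and adjusted p = 0.0042 with an estimated correlation). Slc25a1 fell by 1.94 (SE 0.128) and Acss2, which makes acetyl-CoA from acetate, by 2.38 (SE 0.180).

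Genes of connected pathways fell in KO at 22 °C as well. In cholesterol synthesis 18 of 25 fell (18 fell and 1 rose adjusted over the list alone, adjusted p = 0.0046 with an estimated correlation), with Nsdhl at -1.75 and Pmvk at -1.87. In the pentose phosphate pathway 4 of 7 fell (5 adjusted over the list alone, adjusted p = 0.0329 with an estimated correlation), with Tkt at -1.69 and Pgd at -1.86. In glycogen metabolism 5 of 13 fell (6 fell and 1 rose adjusted over the list alone, adjusted p = 0.0326 with an estimated correlation), with the phosphorylase Pygl at -1.85 and the branching enzyme Gbe1 at -1.16. Of 9 glucose-responsive ChREBP genes 3 fell (6 fell and 1 rose adjusted over the list alone, adjusted p = 0.0250 with an estimated correlation), Pnpla3 (-2.19), Mlxipl (-0.65) and Txnip (-0.60). Srebf1 fell by 0.82 (SE 0.201). With the clock covariate both regulators lost their calls, Mlxipl at -0.86 (adjusted p = 0.179) and Srebf1 at -0.55 (adjusted p = 0.708).

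For 4 further metabolic lists the camera call was lost with an estimated correlation. In glucose uptake and glycolysis 10 of 19 fell (12 fell and 1 rose adjusted over the list alone, adjusted p = 0.0901 with an estimated correlation), with Gpi1 at -1.22 and Gapdh, uncertain as above, at -1.26. In the TCA cycle and pyruvate dehydrogenase list 13 of 19 fell (17 adjusted over the list alone, adjusted p = 0.138 with an estimated correlation), with Pdhb at -1.28 and Pdha1 at -0.74. In oxidative phosphorylation 28 of 55 fell (38 adjusted over the list alone, adjusted p = 0.566 with an estimated correlation), with Sdha at -0.44 and Ndufs1 at -0.42. In fatty acid oxidation 8 of 22 fell (10 fell and 1 rose adjusted over the list alone, adjusted p = 0.663 with an estimated correlation). With the clock covariate the oxidative phosphorylation and fatty acid oxidation lists turned direction in camera (adjusted p = 0.0524 and 0.491), and Sdha (-0.18, adjusted p = 0.685) and Ndufs1 (-0.18, 0.708) lost their calls. With 1 library left out oxidative phosphorylation had 16 lower genes without KO replicate 1 or 3 and 44 without WT replicate 4, and fatty acid oxidation had 4 without WT replicate 1 or 2 or KO replicate 1 or 3, 5 without KO replicate 2 and 11 without WT replicate 4. The thermogenic and brown adipocyte list had 1 gene higher, Ppargc1a (1.16), and 1 lower, Adrb3 (-1.01), of 23 (1 and 1 adjusted over the list alone), and did not pass camera (adjusted p = 0.730). Without WT replicate 1 it had 3 higher, and 2, 3, 2 and 3 were lower without WT replicates 3 and 4 and KO replicates 2 and 4. Ucp1 was 6178 ± 2462 CPM in WT and 7165 ± 1977 CPM in KO, a log2 fold change of 0.21 (SE 0.244, adjusted p = 0.565).

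Some lipid-handling and vascular genes moved the other way. Lpl, lipoprotein lipase, rose by 0.90 (SE 0.127) while Acsl5 fell by 1.59. Fatty acid uptake as a list did not pass (2 of 13 rose and 2 fell, also adjusted over the list alone, adjusted p = 0.760). In triglyceride synthesis 2 of 14 rose and 3 fell (2 and 4 adjusted over the list alone, adjusted p = 0.760), with Agpat2 at -1.02 and Gpd2 at -0.78. The rises in fatty acid uptake became 1 without KO replicate 2, and those in triglyceride synthesis 0 without WT replicate 2 or KO replicate 4 and 1 without WT replicate 3 or 4 or KO replicate 1. Of 12 endothelial markers 5 rose (5 adjusted over the list alone, adjusted p = 0.138 with an estimated correlation), including Tie1 (0.42) and Pecam1 (0.33). The 5 became 3, 3 and 2 without WT replicates 1, 2 and 3 and 2, 3 and 3 without KO replicates 2, 3 and 4. The Pecam1 call was lost with limma-voom (0.23, adjusted p = 0.0718), with only the groups compared (0.33, 0.0928), without muscle-bearing libraries (0.25, 0.108) and with the clock covariate (0.10, 0.887), and that of Tie1 with the clock covariate (0.29, 0.548). Of 10 smooth muscle and pericyte markers 6 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.265 with an estimated correlation), including Rgs5 (0.47) and Tagln (0.67). Akt1 rose by 0.37 (SE 0.082), a call lost, with values of similar size, with only the groups compared (0.37, adjusted p = 0.0673), without muscle-bearing libraries (0.34, 0.0765) and with the clock covariate (0.40, 0.449).

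Some circadian and immediate early genes differed between the genotypes at 22 °C. Dbp, an output gene of the circadian clock, was 25.6 ± 10.4 CPM in WT and 4.29 ± 0.986 CPM in KO (log2 fold change -2.57, SE 0.354), and Arntl rose by 0.90. Of the 16 clock genes 2 rose and 3 fell (3 and 4 adjusted over the list alone, and 6 fell without WT replicate 4 at 22 °C), and the list did not pass camera (adjusted p = 0.192). Of 14 immediate early genes 4 rose (6 adjusted over the list alone). This list passed camera at the preset correlation (adjusted p = 0.0068) but not with an estimated one (0.690), nor at the preset one without KO replicate 1 at 22 °C (0.280), without muscle-bearing libraries (0.225), with limma-voom (0.260) or with the clock covariate (0.711). The 4 became 0 without KO replicate 1 or WT replicate 2 and 1 without WT replicate 3 or 4. KO replicate 1 also had 0.801% of its counts on skeletal muscle markers, and without it Fosb went from 4.78 to 1.10 (adjusted p = 0.287), Fos from 3.16 to 0.27 (0.751) and Dusp5 from 3.20 to 1.46 (0.152). Without WT replicate 2 at 22 °C these were 0.0551, 0.0914 and 0.0511, Fos was at 0.0738 and 0.0732 without WT replicate 3 or 4, and Dusp5 at 0.0600 without WT replicate 3.

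Among genes that passed the level and overlap limits of the naming rule, which Fosb and Fos did not, the largest increases in KO at 22 °C were those of Sgk2 (4.30, SE 0.365), a kinase gene of the same broader family as Akt2, Elmod2 (3.52), Dusp5, Nr4a3 (2.80), Gem (2.71) and Igha (2.71), and the largest decreases those of Adprhl1 (-4.32), Slc2a5 (-3.87), Ttc25 (-3.26), Sorcs2 (-3.14), Fasn and Fer1l6 (-2.82). Means at 22 °C were low in WT for Sgk2 (1.11 CPM), Dusp5 (0.99) and Igha (0.88), and in KO for Adprhl1 (0.83). The sizes of these changes are therefore uncertain. The Gem call was lost with limma-voom (1.48, adjusted p = 0.0942) and with only the groups compared (2.71, 0.0592), that of Igha with limma-voom (3.54, 0.117), and that of Dusp5 with both (1.87, 0.240, and 3.21, 0.0735). With the clock covariate 29 of the 44 genes named as called at 22 °C, leaving out Dbp and Arntl, which define it, lost their call (adjusted p = 0.0536 to 0.990). Their values were -0.18 to 1.63 times those without it (median 0.72), and Fosb and Fos turned direction. At 22 °C the covariate ran from -3.43 to -2.20 in KO and from -0.80 to 1.78 in WT, without overlap. A covariate so tied to genotype widens the errors of the KO effect, so lost calls alone do not show a clock effect. In total 2482 genes changed, 1061 higher and 1421 lower in KO. A fit on only these 8 libraries called 634, leaving out the libraries with muscle transcripts left 1096, and the clock covariate, which differs between the genotypes at 22 °C, left 109.

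At 30 °C the KO differed from WT in 6 genes, 4 higher and 2 lower. Of the 14103 genes tested, 608 had an unadjusted p under 0.05, a share below the 0.05 that tests with no changed gene would give. By edgeR, the genes besides Akt2 were Elmod2 (32.7 ± 3.03 CPM in WT and 141 ± 54.8 CPM in KO, log2 fold change 2.10), Mreg (1.08), Ucp2, a mitochondrial carrier gene (0.62), and, outside the naming rule and chosen after their values were seen, Kcnk2 (1.47) and Akt2-ps (-1.52), a processed copy that can share reads with Akt2. Without WT replicate 2 at 30 °C only 2 genes were called, and Elmod2 (2.11) and Ucp2 (0.61) were then at adjusted p = 0.0586. Elmod2 was also lost with only the groups compared (2.09, adjusted p = 0.0763). Ucp2 was also lost without WT replicate 3 or 4 (0.60 in both, adjusted p = 0.0679 and 0.0693). Kcnk2 kept its call in 3 of the 8 fits that left out 1 library, and without the muscle-bearing libraries 1 gene was called. DESeq2 called 21 genes and limma-voom 44.

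No lipogenesis gene changed at 30 °C by the adjusted p over all genes, and 1 fell adjusted over the list alone. The share of counts on this list was lower, though, at 0.538% to 0.985% per library in KO and 1.08% to 2.49% in WT. This difference in share was not tested. The list had a median of -0.19 and its camera call (adjusted p = 2.54e-04) was lost at adjusted p = 0.288 with an estimated correlation. The oxidative phosphorylation list (median 0.11, adjusted p = 2.08e-06) was lost at adjusted p = 0.724 with an estimated correlation, and none of the other 8 camera calls at 30 °C held with it either (adjusted p = 0.159 to 0.732). Mlxipl (-0.09), Srebf1 (0.04), Ucp1 (0.23) and Akt1 (0.16) did not pass.

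Whether the KO effect differed between temperatures was tested directly as an interaction. The lipogenesis list had the smallest camera p of the 33 lists (adjusted p = 2.31e-25). Of the 16 genes 11 had a lower, that is more negative, KO log2 fold change at 22 °C than at 30 °C (12 adjusted over the list alone, adjusted p = 0.0046 with an estimated correlation). The median interaction of the list was -1.42, with Slc25a1 at -1.83 and Thrsp at -1.94 among the members. The 11 became 7 without WT replicate 4 or KO replicate 1 at 30 °C, 7 with the replicate block, and 4 without muscle-bearing libraries (median -1.45) or with the clock covariate (median -1.50). More negative KO log2 fold changes at 22 °C were also called for 9 of 25 cholesterol genes (17 adjusted over the list alone, adjusted p = 0.0088 with an estimated correlation, Nsdhl -1.63, Pmvk -1.72). The same was called for 4 of 7 pentose phosphate genes (5 adjusted over the list alone, adjusted p = 0.0250 with an estimated correlation, Tkt -1.71, Pgd -1.80). It was also called for 5 of 13 glycogen genes (6 adjusted over the list alone, adjusted p = 0.0326 with an estimated correlation, Pygl -1.96, Gbe1 -1.14) and 1 of 9 ChREBP genes (3 adjusted over the list alone, adjusted p = 0.0326 with an estimated correlation, Pnpla3 -1.98, and 2 without WT replicate 2 at 22 °C). In glycolysis 9 of 19 genes (13 adjusted over the list alone, adjusted p = 0.0743 with an estimated correlation) and in the TCA list 8 of 19 (17 adjusted over the list alone, adjusted p = 0.120 with an estimated correlation) were lower, with Gpi1 at -1.30, Pkm at -1.15, Pdha1 at -0.81 and Pdhb at -1.26. Of the oxidative phosphorylation genes 8 of 55 were lower (41 adjusted over the list alone, adjusted p = 0.414 with an estimated correlation). Those 8 became 0 to 3 without any single library at 30 °C, 1 or 2 without any KO library at 22 °C, and 4, 13, 13 and 32 without WT replicates 1 to 4 at 22 °C. In fatty acid oxidation 2 of 22 were lower (11 lower and 1 higher adjusted over the list alone, adjusted p = 1.50e-05, and 0.478 with an estimated correlation) and in branched-chain amino acid catabolism 2 of 17 (6 adjusted over the list alone, 0.0022 and 0.612). The first became 1 without any WT library or KO replicate 1, 3 or 4 at 30 °C or KO replicate 2 or 3 at 22 °C. It became 9 without WT replicate 4 at 22 °C. The second became 0 or 1 without any library except WT replicates 2 and 3 at 22 °C, which left it at 2, and WT replicate 4 at 22 °C, which made it 6. With the clock covariate the first lost its camera call (0.452) and the second turned direction (0.503). No immediate early gene passed, and that list's camera call (0.0467, and 0.787 with an estimated correlation) was lost in 6 of the 16 fits that left out 1 library. These left out WT replicate 1 or KO replicate 1 or 3 at 30 °C, or WT replicate 3 or 4 or KO replicate 1 at 22 °C (0.992 for the last). In the TCA list 5 were lower without WT replicate 1, 3 or 4 or KO replicate 1 or 3 at 30 °C or KO replicate 2 or 3 at 22 °C. Without muscle-bearing libraries the cholesterol, pentose phosphate, glycogen, glycolysis, TCA and oxidative phosphorylation counts were 1, 0, 1, 0, 0 and 0, and with the clock covariate 4, 0, 1, 0, 0 and 0.

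In total 443 genes had an interaction, 106 positive and 337 negative, and the count depended on the libraries and the tool. DESeq2 called 1070 and limma-voom 1050, no filter gave 236, leaving out the muscle-bearing libraries gave 15, all negative, and the clock covariate 29. With 1 library left out the count ran from 147 (without KO replicate 1 at 30 °C) to 1085 (without WT replicate 4 at 22 °C). The other libraries that moved it by over 1.5 times were WT replicates 1 to 4 at 30 °C (184, 223, 205 and 159), KO replicates 3 and 4 at 30 °C (166 and 218) and KO replicates 2, 3 and 4 at 22 °C (205, 190 and 245). The interactions of Ucp1 (-0.02), Akt1 (0.21), Mlxipl (-0.56, adjusted p = 0.0923) and Srebf1 (-0.86, adjusted p = 0.102) did not pass.

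Of the 2897 genes higher at 22 °C in WT, 934 were among the 1421 lower in KO at 22 °C. Independent lists of those sizes would share 292. Both comparisons use the WT libraries at 22 °C, which alone makes their fold changes correlate: the correlation across genes, which are not independent replicates, was -0.569, against -0.540 to -0.454 (median -0.491) in 20 simulations with no changed genes. The covariance was -0.288, against a median of -0.0601. With the WT libraries at 22 °C divided between the comparisons, the 6 divisions shared 367 to 1084 genes (median 499.5), against 107 to 290 for independent lists.

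On chromosome 8 (GRCm38), the genes on either side of Ucp1 (83290352 to 83298452) rose in KO at 22 °C. Elmod2 (83312632 to 83332486, minus strand) was 37.7 ± 9.30 CPM in WT and 433 ± 99.8 CPM in KO at 22 °C (log2 fold change 3.52, SE 0.302, adjusted p = 3.14e-06). Tbc1d9 (83165352 to 83272934, plus strand) was 9.10 ± 2.70 and 26.8 ± 2.70 CPM (1.55, SE 0.189, adjusted p = 8.54e-05), and at 30 °C its log2 fold change was 0.90 (adjusted p = 0.271). Of the 6 tested Ucp1 neighbours fixed as a list, 2 rose and 2 fell at 22 °C (2 and 2 adjusted over the list alone, adjusted p = 0.404 with an estimated correlation), and at the preset correlation the call was lost without WT replicate 2 or 3 at 22 °C (adjusted p = 0.141 and 0.0569). Without WT replicate 1 or 4 or KO replicate 3 1 fell. From 30 °C to 22 °C, Elmod2 rose by 1.62 and Tbc1d9 by 1.02 in KO, while their interactions of 1.42 and 0.65 did not pass (adjusted p = 0.0604 and 0.179).

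**Figure D3:**
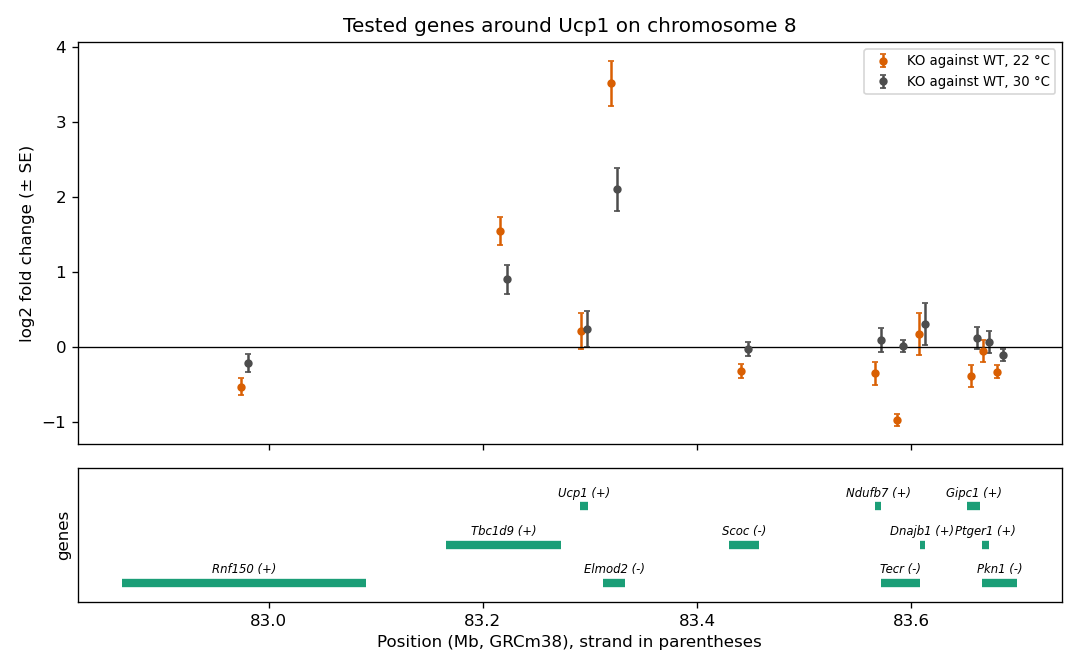
Log2 fold change of KO against WT with its standard error (upper panel) for the tested genes around Ucp1, by position in Mb on chromosome 8 of GRCm38, and the genes' extents (lower panel). Elmod2 at 3.52 and Tbc1d9 at 1.55 stand above the other genes drawn at 22 °C, and Ucp1 between them is at 0.21.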

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

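The tests weighed for the 3 patterns here were chosen after the results were seen, while the counts over regrouped libraries were fixed before they were run, except those of gene lists with an estimated correlation.

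Regrouping the libraries gave smaller gene counts in nearly every case. For KO against WT at 22 °C, 1 of the 35 splits of the 8 libraries, the real one, reached 2482 genes, and the highest other gave 88. At 30 °C 1 of 35 reached 6 genes and the highest other gave 0. For temperature 1 of 35 reached 5406 genes in WT and 1 of 35 reached 3772 in KO, with 1 gene as the highest other in each. Chance can be excluded for the counts in KO at 22 °C and for temperature in each genotype at a share under 0.05. At 30 °C the 6 genes included the deleted gene Akt2 and its copy Akt2-ps, which alone would place the real split first. The splits therefore cannot show whether the other genes called at 30 °C stand apart from chance. All 4 genes higher in KO at 30 °C were also called higher at 22 °C, against 0.301 for independent lists. The 2 lower genes were also lower there. These comparisons use different libraries, although 1 model estimated the spread for both. This argues against chance for the 4 higher genes as a set. For the interaction 4 of 100 reassignments of genotype within temperature reached 443 genes. The 3 others all kept the real genotypes at 22 °C and gave more genes than the real labels (481, 863 and, as the highest other, 947). These reassignments therefore test for any effect of genotype, and do not show that it differed between the temperatures.

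The number of gene lists called with the preset correlation did not stand out from regrouped libraries. Adjusted over the 33 lists of each comparison, as many lists came in 10 of 35 splits for KO at 22 °C (real 14, highest other 19), 16 of 35 for KO at 30 °C (10, highest other 14), 8 of 35 for temperature in WT (18, highest other 22), 4 of 35 for temperature in KO (17, highest other 17) and 54 of 100 for the interaction (10, highest other 19), so chance cannot be excluded for those numbers. With an estimated correlation, as many came in 1 of 35 for KO at 22 °C (real 5, highest other 1) and 1 of 35 for temperature in WT (5, highest other 0), where chance can be excluded. For the interaction 1 of 100 came to as many (6, highest other 5), with 5, 4 and 3 in the 3 draws that kept the genotypes at 22 °C, which is limited in the same way. Chance cannot be excluded for KO at 30 °C and for temperature in KO, where the real count was 0, reached in 35 of 35, and the highest other was 1.

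The first pattern is the lower lipogenic expression in KO at 22 °C. The share of counts left to genes outside the 50 most abundant and this list had a log2 ratio of 0.030 between KO and WT at 22 °C (-0.08 to 0.11 over the pairs of libraries), against a list median of -1.77, which argues against distorted scaling. A share of brown adipocytes low enough to give this fall would lower their identity genes alike. The median of that list, which also holds thermogenic genes, was -0.14 with a spread of 0.42 (median absolute deviation). A smaller shift in cell types stays open. Of the endothelial markers 5 rose and 0 fell, and of the smooth muscle and pericyte markers 6 rose and 1 fell. Of the macrophage and lymphocyte markers 0 rose and 0 fell. Another collection time or feeding state in this group cannot be told apart from the knockout, because the clock genes differed with genotype at 22 °C: within groups the Dbp minus Arntl index and the mean lipogenic log2 CPM correlated at r = -0.21 (permutation p = 0.431, 0.08 without the 2 farthest libraries), and with the clock covariate the list median was -1.62 with 7 of 16 genes called. An effect of AKT2 loss stays open beside it.

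The second pattern is the higher Elmod2 and Tbc1d9 in KO. Transcription reading on from the resident Ucp1 gene is argued against for Tbc1d9, which lies before the start of Ucp1 on the same strand and was higher by 1.55 (SE 0.189). A change of the whole region is argued against by 5.56% of the 72 other genes within 3 Mb being higher, against 7.52% of all genes (upper 95% limit of the region's share 13.6%). A candidate explanation is that the Ucp1-driven Cre transgene carries extra copies of the genes next to Ucp1, since the genes on both sides were higher and Elmod2 rose with the lower temperature in KO by 1.62, as Ucp1 does, but had a log2 change of 0.20 in WT (adjusted p = 0.590), although the difference between the genotypes did not pass (interaction 1.42, adjusted p = 0.0604). For Elmod2, reading on from Ucp1 at an equal rate in both genotypes is argued against by the WT levels. In WT Elmod2 was 32.7 ± 3.03 CPM at 30 °C and 37.7 ± 9.30 CPM at 22 °C. Ucp1 there went from 1518 ± 92.2 to 6178 ± 2462 CPM. At 22 °C Ucp1 was 7165 ± 1977 CPM in KO, where Elmod2 was 433 ± 99.8 CPM. Reading on in KO alone cannot be told apart from extra copies: the excess of Elmod2 in KO was 5.52% of the Ucp1 level at 22 °C and 6.04% at 30 °C. Elmod2 lies past Ucp1 on the other strand, and neither the strand setting nor reads between the genes are given. The labels give neither the transgene status of the WT littermates nor whether they had tamoxifen. An effect of AKT2 loss itself, or of tamoxifen, was therefore not separated from extra copies.

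The third pattern is skeletal muscle transcripts in some libraries. The muscle genes rose and fell together over the 16 libraries (median pairwise correlation 0.97, and 0.96 without the 2 farthest), which is what muscle carried over with the fat would give. Of the 5 libraries with over 0.1% of counts on muscle markers, 4 were at 30 °C, 2 of each genotype. At 22 °C carry-over and an effect of the knockout cannot be told apart, since 2 of the 4 KO libraries (0.801% and 0.0836%) were above every WT library (highest 0.0355%) and the other 2 (0.0064% and 0.0060%) were within the WT range. KO replicate 1 at 22 °C was far from the other 3 in this share (gap over range 0.902).

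Single libraries also stood apart in genes named in the text, where the gap to the nearest of the other 3, over the range of the group, passed Dixon's limit in 21 of 340 groups tested, and chance gives about 1 in 20. Of 16 groups of library measures 1 passed it, the muscle share above. In KO replicate 1 at 22 °C this held for Ucp1 (0.832), Agpat2 (0.844), Lpl (0.982), Pdhb (0.899), Elmod2 (0.860) and Cntfr (0.872), all low. Other KO libraries at 22 °C were replicate 2 for Srebf1 (0.915) and Kif11 (0.896), replicate 3 for Usp18 (0.890) and replicate 4 for Spag5 (0.844). In KO at 30 °C they were replicate 1 for Slc25a1 (0.846), Sgk2 (0.915) and Acly (0.894), replicate 2 for Adprhl1 (0.892) and replicate 4 for Elmod2 (0.868) and Nnmt (0.918). In WT they were replicate 1 for Elmod2 (0.870), replicate 2 for Adrb3 (0.833) and replicate 3 for Slc25a1 (0.939) at 30 °C, and replicate 3 for Dusp5 (0.928) and Ctss (0.871) at 22 °C.

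The KO effect differed between the temperatures in 443 genes by the interaction test, 36 of them named in the text. Positive log2 interactions were those of Igha (3.55), Sgk2 (3.37), Cntfr (2.28), Nnmt (2.19), Cldn1 (1.71), Smad3 (1.68) and Lpl (0.78). Negative ones were those of Adprhl1 (-4.31), Ttc25 (-2.85), Sorcs2 (-2.75), Acly (-2.47), Dbp (-2.22), Acss2 (-2.18), Fasn (-2.13), Acot11 (-2.09), Acsl5 (-1.99), Pnpla3 (-1.98), Pygl (-1.96), Thrsp (-1.94), Slc25a1 (-1.83), Pgd (-1.80), Pmvk (-1.72), Tkt (-1.71), Nsdhl (-1.63), Gpi1 (-1.30), Pdhb (-1.26), Gapdh (-1.25), Pkm (-1.15), Gbe1 (-1.14), Elovl6 (-1.13), Pdha1 (-0.81), Ldha (-0.72), Pdhx (-0.72), Sdhd (-0.49), Ndufs1 (-0.45) and Sdha (-0.44). Of the 36 calls, 24 were kept in each of the 16 fits that left out 1 library. Without the 5 muscle-bearing libraries 30 were lost, with all 7 positive ones among them (adjusted p = 0.0561 to 0.281). The 36 log2 values were then 0.76 to 1.27 times those from all libraries (median 0.94), with 11 libraries left. With the clock covariate 28 of 35 were lost, leaving out Dbp, which defines it, again with all 7 positive ones (0.0859 to 0.449, median 0.86 times), with the replicate block 10, with no filter 3, with upper-quartile factors and with the muscle covariate 2 each, and with limma-voom 1.

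The other 12 of these interactions were lost when single libraries were left out, at 0.69 to 1.12 times their log2 values from all libraries (median 0.99). Fasn was lost in 7 of 16 fits, without WT replicate 2 or 4 or KO replicate 1 or 4 at 30 °C and without KO replicate 2, 3 or 4 at 22 °C (adjusted p = 0.0544 to 0.0746). Elovl6 was lost without WT replicate 1 or 4 or KO replicate 1 at 30 °C (0.0514 to 0.0626), and Ttc25 without WT replicate 4 or KO replicate 1 at 30 °C (0.0510 and 0.0592). Dbp was lost without WT replicate 1, 3 or 4 or KO replicate 1 at 30 °C or KO replicate 3 at 22 °C (0.0510 to 0.0575). Lpl was lost without any WT library or KO replicate 1, 3 or 4 at 30 °C or KO replicate 2, 3 or 4 at 22 °C (0.0565 to 0.0859). Sdha and Ndufs1 were lost without any library at 30 °C or KO replicate 1, 2 or 3 at 22 °C (0.0528 to 0.0883 and 0.0508 to 0.0819), and Sdhd without any library at 30 °C, any KO library at 22 °C or WT replicate 1 at 22 °C (0.0567 to 0.104). Ldha was lost without WT replicate 1, 2 or 4 or any KO library at 30 °C, WT replicate 1 at 22 °C or KO replicate 2, 3 or 4 at 22 °C (0.0532 to 0.0876). Igha was lost without WT replicate 1 or 2 or any KO library at 30 °C, WT replicate 2 at 22 °C or KO replicate 2, 3 or 4 at 22 °C (0.0504 to 0.0757). Cldn1 was lost without any WT library or KO replicate 1, 2 or 4 at 30 °C, WT replicate 2 at 22 °C or KO replicate 2, 3 or 4 at 22 °C (0.0527 to 0.0873). Adprhl1 was lost without WT replicate 1, 3 or 4 or KO replicate 1, 2 or 3 at 30 °C, WT replicate 1 at 22 °C or KO replicate 2, 3 or 4 at 22 °C (0.0507 to 0.178).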

How the results depend on the processing

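The muscle, clock and abundant-gene alternatives were chosen after the data were seen. The cause of each difference was not tested. For fits on fewer libraries, lower power was not separated from an effect of the libraries left out. The clock covariate did not overlap between the genotypes at 22 °C, so calls lost with it can come from lower power alone. For KO at 22 °C the 2482 genes became 634 with only the groups compared, 1096 without muscle-bearing libraries and 109 with the clock covariate, and 1936 to 3080 with 1 library left out. For KO at 30 °C the 6 genes became 21 with DESeq2, 44 with limma-voom, 1 without muscle-bearing libraries and 2 to 7 with 1 library left out. For temperature in WT the 5406 genes became 3386 without muscle-bearing libraries and 4509 to 5570 with 1 left out. For temperature in KO the 3772 became 6067 with limma-voom, 1755 without muscle-bearing libraries, 2215 with the clock covariate and 2729 to 3838 with 1 left out. The 443 interactions became 236 with no filter, 1070 with DESeq2, 1050 with limma-voom, 15 without muscle-bearing libraries, 29 with the clock covariate and 147 to 1085 with 1 left out. The overlap of 934 genes became 386 without muscle-bearing libraries, 61 with the clock covariate and 499.5 with the WT libraries at 22 °C split. Of the 147 calls named singly, the 36 interactions included, 39 were lost without muscle-bearing libraries, 12 with the replicate block, 7 with limma-voom, 4 with the muscle covariate, 3 each with no filter and upper-quartile factors, 1 with DESeq2 and 7 of 111 with only the groups compared. With the clock covariate 58 of 144 were lost, leaving out Dbp and Arntl, which define it. The 68 list calls became 13 with an estimated inter-gene correlation. Relative-log-expression factors, the stricter filter, the muscle covariate and the factors without abundant genes kept all 5 counts within 1.5 times.

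The labels do not say that the replicate number pairs the libraries, and the correlations leave it open. Same-numbered libraries correlated from -0.503 to 0.519 (median 0.169, against -0.036 for different numbers), 13 of 24 pairs over 0.1. The 6 pairs of replicate 3 were at 0.185 to 0.519, while the medians of the other numbers were -0.014, 2.50e-04 and 0.0016, and 1 of 16 libraries was closest to one of its own number. With the replicate block 2092, 6, 5169, 3406 and 186 genes were called in KO at 22 °C, KO at 30 °C, temperature in WT, temperature in KO and the interaction.

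Directions turned for called genes in KO at 22 °C under the clock covariate alone: Acad8 (0.068), Atf4 (-0.015), Cdh5 (-0.067), Fosb (-0.85), Fos (-0.26) and Egr1 (-0.15). Arntl (-0.074) is no evidence there, because it defines the covariate. Lists that turned there were fatty acid oxidation (adjusted p = 0.491) and oxidative phosphorylation (0.0524) in KO at 22 °C and branched-chain amino acid catabolism (0.503) in the interaction. The other turns were in genes not called. In KO at 30 °C Srebf1 was -0.49 without muscle-bearing libraries and ran from -0.20 (without KO replicate 1) to 0.18 (without KO replicate 4), with -0.051 without WT replicate 2. For temperature in KO, Akt1 was -0.080 with upper-quartile factors, -0.014 with limma-voom and from -0.034 (without KO 22 °C replicate 2) to 0.078 (without KO 22 °C replicate 3) with 1 library left out, with -0.022 without KO 30 °C replicate 4, and -0.0011 and -0.0038 without KO 22 °C replicates 1 and 4. There Srebf1 was 0.085 without muscle-bearing libraries. In the interaction Akt2 ran from -0.050 (without KO 30 °C replicate 4) to 0.14 (without KO 30 °C replicate 1), with -0.0021 without WT 30 °C replicate 3. Ucp1 was 0.42 with limma-voom, 0.016 with the replicate block, 0.24 without muscle-bearing libraries, 1.06 with the clock covariate, 0.029 and 5.21e-04 without KO 30 °C replicates 1 and 2, 0.20 and 0.11 without WT 22 °C replicates 1 and 2, and 0.15 without KO 22 °C replicate 1. No fit was run at a lower depth, so what depth limits was not tested. Interactions of 1.5-fold were recovered in 4 of 100 simulated genes, with 200 genes changed in all.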

Other observations

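The test of a hypothesis here was chosen after the fold changes had been seen.

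Few members of the other cell type and stress lists passed the test in KO against WT at 22 °C. None of 14 macrophage markers (adjusted p = 0.772), 11 lymphocyte markers (0.938), 10 preadipocyte and fibroblast markers (0.389), 10 Schwann cell and nerve markers (0.179), 5 red blood cell genes (0.761) or 16 skeletal muscle markers (0.148) passed singly, over all genes or adjusted over the list alone. Of the 7 white adipocyte markers 1 fell (1 adjusted over the list alone, adjusted p = 0.798), of the 17 extracellular matrix genes 3 rose and 1 fell (3 and 1 adjusted over the list alone, 0.206), of the 23 proliferation genes 1 fell (0 adjusted over the list alone, 0.761) and of the 16 interferon genes 1 rose (0 adjusted over the list alone, adjusted p = 0.0091, and adjusted p = 0.690 with an estimated correlation, and 0.0576 at the preset one without WT replicate 1 at 22 °C). The insulin signalling list had 4 of 18 genes higher and 1 lower, Mtor at -0.80 (5 and 1 adjusted over the list alone, adjusted p = 0.418 for the list, with 2 higher without WT replicate 2 or KO replicate 1, 3 lower without WT replicate 2 and 2 lower without KO replicate 4). The FoxO target list had 3 of 17 lower (4 lower and 1 higher adjusted over the list alone, 0.387, and 1 lower without WT replicate 2 or KO replicate 2 or 4), the unfolded protein list 2 of 17 higher and 2 lower (3 and 2 adjusted over the list alone, 0.815, with 0 higher without WT replicate 3 or KO replicate 1 and 1 without WT replicate 1 or 2 or KO replicate 2), and the lipolysis list 1 of 13 higher and 2 lower (2 and 2 adjusted over the list alone, 0.705, with 0 higher without WT replicate 3 or KO replicate 1 or 4, 2 higher without WT replicate 1 and 4 lower without WT replicate 4). The single genes were lost without WT replicate 3 for white adipocytes, without WT replicate 1 or 4 or KO replicate 2, 3 or 4 for the lower matrix gene, without any library except WT replicate 1 and KO replicate 2 for proliferation, and without WT replicate 1, 2 or 4 or KO replicate 2 for interferon, where 2 rose without KO replicate 3. Of 17 branched-chain amino acid genes 7 fell and 1 rose (7 and 1 adjusted over the list alone, 0.0650). None of 8 mitochondrially encoded genes, uncertain because of nuclear copies, passed (0.179).

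Cntfr, which encodes a cytokine receptor, had a positive interaction. It was 56.6 ± 10.2 CPM in WT and 59.2 ± 13.8 CPM in KO at 30 °C, and 11.2 ± 4.22 CPM in WT and 57.4 ± 11.5 CPM in KO at 22 °C. Nnmt was 27.7 ± 7.81, 22.1 ± 3.60, 28.6 ± 12.8 and 104 ± 25.7 CPM in the same order. Both interactions lost their call, but not their size, without muscle-bearing libraries (Cntfr 2.15, adjusted p = 0.0574, and Nnmt 2.10, 0.281, against 2.28 and 2.19) and with the clock covariate (2.57, 0.0859, and 3.12, 0.101).

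One hypothesis was that the changes seen in KO at 22 °C may be present in a weaker form at 30 °C. Of the 2481 genes called at 22 °C other than Akt2, 56.4% had the same direction at 30 °C. Among the 70 labellings of the 30 °C libraries 24 gave as high a share, up to 73.1%, so the data do not separate this share from chance.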
